A study of Leishmania major strain Friedlin with 5 samples.

How the data were processed

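The series holds 5 samples of Leishmania major: 2 size fractions of short nascent strands (F4 and F5), 1 genomic DNA control and 2 mononucleosomal DNA libraries. Per the labels' protocols, DNA from isolated nuclei was denatured, separated on a sucrose gradient and digested repeatedly with lambda exonuclease before the strands were made double-stranded and sequenced. Nucleosomal DNA was cut out of agarose gels after MNase digestion, per the labels' protocols. Per the submitters' processing notes, Bowtie 1.0.0, BWA, SAMtools 0.1.19, bedtools 2.7.0 and MACS2 2.1.0.20140616 were used, and the notes as used here give no role or order for them. The genome build was not given in the sources used here. The labels describe the genomic DNA as the control for peak calling. Its reads were not analysed here.

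The deposited files of the authors hold intervals with no score, count or other signal: the start and end of each peak in 1 list per fraction, and the start and end of each sequenced fragment in 1 file per nucleosome library. The fragment files are not scaled to depth. Identical peak widths within each list, 800 bp for F4 and 1200 bp for F5, mean that neither height nor width could rank the peaks. Strand and mapping quality of fragments were not used here, so fragments from repeated sequence could not be filtered. Peaks of a fraction depend on its read depth, which is unknown here, and this limits any comparison of peak numbers between fractions. Both labels and series text call the fractions replicates, but they differ in strand size.

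Peaks overlapping by at least 1 bp were counted as shared. Overlaps of F4 with F5 peaks were merged into common sites, and the middle of each was taken as its centre. Random placements kept the number of peaks or sites per chromosome and allowed only the 1 kb windows that both nucleosome libraries covered at 20% or more of the median window, 32592 of 32833 windows (99.3%). Densities refer to the stretch of each chromosome that the fragments reach, 32.9 Mb in all. Overlap and spacing were tested against 10000 placements. Correlations over the 36 chromosomes used 100000 resamples, with Benjamini-Hochberg adjustment over 3 relations. All tests were two-sided permutation tests.

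The middle of each fragment was taken as the nucleosome centre. For each library the mean number of such midpoints within 100 bp of site centres was divided by the mean at 500 to 1000 bp, and the log2 ratio was compared with 1000 sets of random sites. Mean and SD were taken over the 2 libraries. A pseudocount of 1 was added for medians over sites and for the share of all sites with a dip, but not for the chromosome 1 sites. Depleted regions were sought in midpoints smoothed over 101 bp and divided by a local mean. This local mean was taken over 2001 bp and then smoothed once more. Peaks of a single fraction were compared with shared ones by permuting the status of peaks 10000 times. Depth along chromosomes was taken as the median of 1 kb windows in bins of 20 kb. Shares carry 95% Wilson intervals.

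The tests and the alternatives were fixed before the data were examined, apart from those named as added later. Named sites were the 10 widest common sites, as the rule set for lists without scores, and chromosome 1 as a worked example. Chromosomes 8, 12, 23, 27, 31 and 34 and the stretches without sites were chosen after their values were seen, and so were the tests of long stretches, depleted regions and the difference between fractions. Fragment length classes were added after the lengths in the libraries were seen, but before the ratios of the classes were. Alternatives covered the overlap rule, the random placement, the use of a single fraction or library, repeated positions, whole-fragment coverage, window sizes, fragment length and averaging over sites.

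The calculations were tested on simulated data. Over 500 sets of 4155 random sites in replicate 2, the nucleosome test called 7.4% at a threshold of 0.05. A planted log2 change of -0.32 at 4155 sites was recovered as -0.31 in both libraries. Among 5483 simulated F5 peaks, a planted share of 39.7% beside F4 peaks was recovered as 41.2%. Correlations of unrelated values over 36 chromosomes were called in 4.2% of 500 draws. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.

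Comparisons that need gene positions, strand or sequence were not run, because the peak lists name no build and the gene table at hand gives no strand. These were the position of sites relative to coding sequences, strand switch regions and gene starts, nucleosomes at gene starts, matched gaps between genes, base composition and gene lists.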

Results

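Replication initiation and nucleosome positions were mapped in exponentially growing promastigotes, the flagellated insect stage, of the parasite Leishmania major strain Friedlin. Short nascent strands, the newly made DNA at places where replication has just begun, were separated by size into the fractions F4 and F5, of which F5 held the longer strands per the series design text. Each fraction was treated with lambda exonuclease, an enzyme that removes DNA lacking the RNA primer of a nascent strand, and gave 1 list of peaks. Mononucleosomal DNA was sequenced in 2 replicate libraries after digestion of chromatin with micrococcal nuclease (MNase), which cuts the DNA between nucleosomes. The labels of the second library differ, since its title names it replicate 2 and its description replicate 1, and the title was followed. A genomic DNA control from stationary phase served in peak calling per the labels, and was not analysed here.

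The F4 list held 6885 peaks, or 210 per Mb, and the F5 list held 5483 peaks, or 167 per Mb. Peaks carried no score. Every F4 peak was 800 bp wide and every F5 peak 1200 bp. Nucleosome replicate 1 held 76176788 fragments with a median length of 167 bp, and replicate 2 held 83717687 with a median of 155 bp. Fragments of 180 bp and over made up 30.1% of replicate 1 and 4.72% of replicate 2. Mean coverage was 396 fragments per base in replicate 1 and 391 in replicate 2. Across 32833 windows of 1 kb, which are not independent samples, fragment midpoints of the libraries correlated with Pearson's r of 0.84 and Spearman's rho of 0.77. With 2 nucleosome libraries and 1 list per fraction, and no statement that they came from separate cultures, the errors given here measure the spread between these libraries, which may be technical. Sites and positions are not replicate cultures, and intervals over them cover counting error only. Coordinates are those of the peak lists, counted from 1. The genome build was not given in the sources used here, so no gene is named and no annotation is given.

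The first comparison asked whether both size fractions marked the same places. Most F5 peaks lay on an F4 peak: 4848 of 5483, or 88.4% (95% Wilson interval 87.5 to 89.2%). Random placement of the peaks within chromosomes gave 34.9% on average, so the overlap was 2.53-fold above random. Of the F4 peaks, 5100 of 6885 met an F5 peak, or 74.1% (73.0 to 75.1%), against 29.4% at random. The two-sided permutation p was 0.0001 for each share, the smallest that the 10000 placements can give. F4 alone held 1785 peaks and F5 alone held 635.

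The places where both lists overlapped merged into 4155 common initiation sites, or 126 per Mb, and covered 10.8% of the genome. The name follows the nascent strand protocol. Both fractions were treated with lambda exonuclease, so their overlap alone does not show that replication began there. Base composition of the peaks was not tested. A single F4 peak paired with a single F5 peak at 2783 of the common sites (67.0%). At the other 1372 sites several peaks had run together. Over all F4 peaks that met an F5 peak, at either kind of site, the nearest midpoints differed by a median of 17 bp. Of these F4 peaks, 80.2% had their nearest F5 midpoint within 100 bp. The widest site spanned 2786 bp on chromosome 25 (506317 to 509102) and was built from 5 F4 peaks and 3 F5 peaks. Next came chromosome 27 at 660649 to 663410 (2762 bp), chromosome 21 at 343017 to 345599 (2583 bp), chromosome 9 at 364116 to 366657 (2542 bp) and chromosome 5 at 342655 to 345165 (2511 bp). The 10 widest were completed by chromosome 10 at 266880 to 269352, chromosome 17 at 45614 to 48009, chromosome 5 at 458027 to 460301, chromosome 21 at 652414 to 654643 and chromosome 31 at 1047962 to 1050160. Nucleosome fragment midpoints across the chromosome 27 site were at 0.692 of the genome mean in replicate 1 and 0.529 in replicate 2. Across the chromosome 25 site they were at 1.03 and 0.972.

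Longer chromosomes held more sites but at lower density. The number of common sites rose with chromosome length over the 36 chromosomes (r = 0.84, rho = 0.81), and r was 0.75 without the 2 chromosomes farthest from the median length. Density fell with length (r = -0.73, rho = -0.77), and r was -0.74 without those 2. It ranged from 212 sites per Mb on chromosome 1 to 79.1 on chromosome 30, a 2.68-fold span. Chromosomes 1 to 5 together had 198 sites per Mb, and chromosomes 32 to 36 had 88.9. The ratio of F5 to F4 peaks fell as well (r = -0.76, rho = -0.81; r = -0.77 without the same 2), from 1.01 over chromosomes 1 to 5 to 0.642 over chromosomes 32 to 36. Each of these 3 relations had a two-sided permutation p of 1e-05 for r and for rho, the smallest that 100000 resamples can give, and a Benjamini-Hochberg value of 1e-05. Density and the F5 to F4 ratio were added to the family after the counts per chromosome were seen. Two-sided tests of density per fraction gave rho = -0.58 for F4 (permutation p = 0.0003) and rho = -0.80 for F5 (permutation p = 1e-05). The nucleosome depth of chromosomes other than 23 and 31 also fell with length, with rho = -0.53 in replicate 1 (permutation p = 0.0015) and rho = -0.86 in replicate 2 (permutation p = 1e-05).

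**Figure D1:**
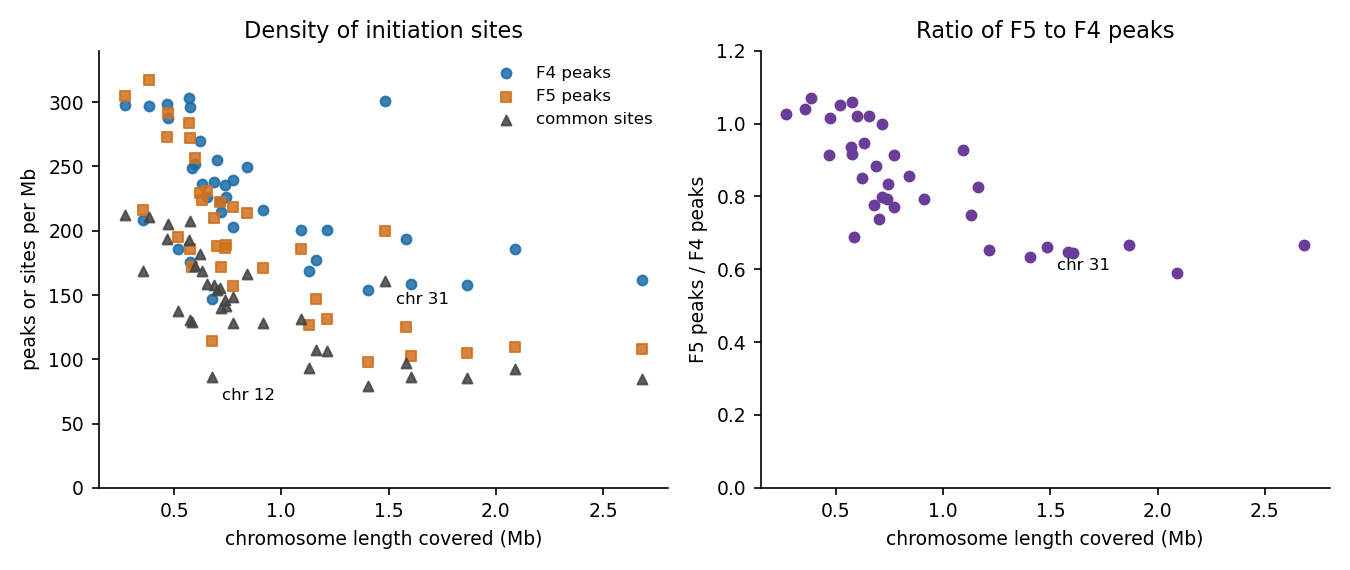
Peaks or common sites per Mb (left) and the ratio of F5 to F4 peaks (right) against the covered length of each chromosome in Mb; each point is 1 of 36 chromosomes. Common sites per Mb fall from 212 on chromosome 1 to 79.1 on chromosome 30, and chromosome 31 lies above chromosomes of like length.

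Chromosome 31 stood above this trend and chromosome 12 below it. Chromosome 31 had 161 common sites per Mb, 1.61-fold the density that a line through the other 35 chromosomes gave for its length, the highest ratio of all 36. Chromosome 12 lay at 0.585-fold its expected density, and chromosome 23 at 0.932-fold. In nucleosome library depth, chromosomes 31 and 23 stood apart from the rest. The median window of chromosome 31 was at 1.92 times the genome median in replicate 1 and 1.90 times in replicate 2. Chromosome 23 was at 1.57 in replicate 1 and 1.03 in replicate 2. The other 34 chromosomes lay between 0.914 and 1.07 in replicate 1 and between 0.864 and 1.19 in replicate 2.

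**Figure D2:**
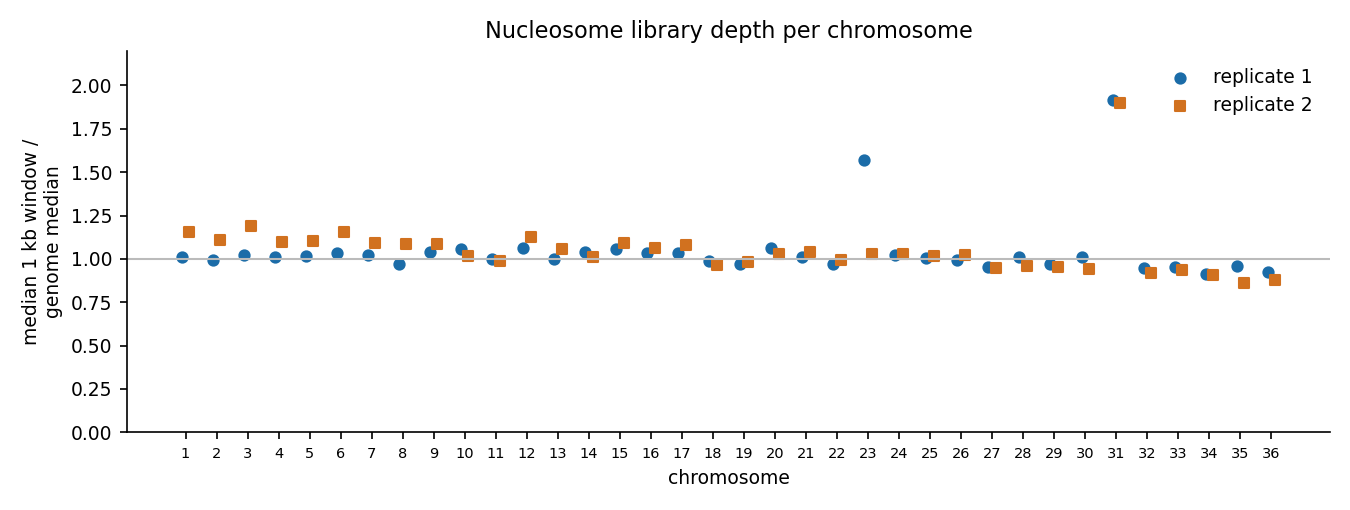
Median fragment midpoints per 1 kb window of each chromosome over the genome median, for nucleosome replicates 1 (circles) and 2 (squares). Chromosome 31 is at 1.92 and 1.90, and chromosome 23 at 1.57 in replicate 1 and 1.03 in replicate 2.

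The spacing of sites along chromosomes was then compared with random placement, to ask whether sites were clustered or regular. Neighbouring sites lay closer together than random ones, with a median distance of 4450 bp against 5142 bp (random range 4857 to 5476 bp). Their distances also varied more, with a coefficient of variation of 1.34 against 1.08 (1.02 to 1.16). The two-sided permutation p was 0.0001 for both, the smallest that 10000 placements can give. The quartiles of the distances were 2180 and 8895 bp, and the smallest was 410 bp. Only stretches that overlapped were merged, so F4 peaks side by side on 1 F5 peak could count as neighbouring sites. How far this added to the clustering was not tested. On chromosome 1, the shortest, 57 sites lay between positions 12394 and 265241, at a median distance of 2871 bp. Its widest site spanned 2069 bp at 238158 to 240226, next to its longest stretch without a site centre, 17777 bp from 239192 to 256969.

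Some long stretches held no common site. There were 30 distances over 50 kb between neighbouring sites, against 15.8 at random (7 to 28; two-sided permutation p = 0.001, the smallest that 1000 placements can give). The longest ran for 203 kb on chromosome 12, from 360453 to 563522, and held 1 F4 peak and no F5 peak. The longest random distance over those placements was 171862 bp. On chromosome 34 a stretch of 186 kb (688870 to 874978) held 1 F4 peak and no F5 peak. On chromosome 8 a stretch of 110 kb (282931 to 393405) held no peak of either list, although nucleosome fragments covered it at 0.93 and 1.10 times the genome median. A stretch of 108 kb on chromosome 27 (966301 to 1074709) was poorly covered, with 70.1% of its windows usable and a depth of 0.882 in replicate 1 and 0.317 in replicate 2. The 30 stretches together held 80 F4 peaks and 23 F5 peaks, and 17 of them held no F5 peak. The chromosome 12 stretch had high nucleosome depth, 1.56 times the genome median in replicate 1 and 2.01 times in replicate 2. Outside that stretch chromosome 12 had 123 common sites per Mb.

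**Figure D3:**
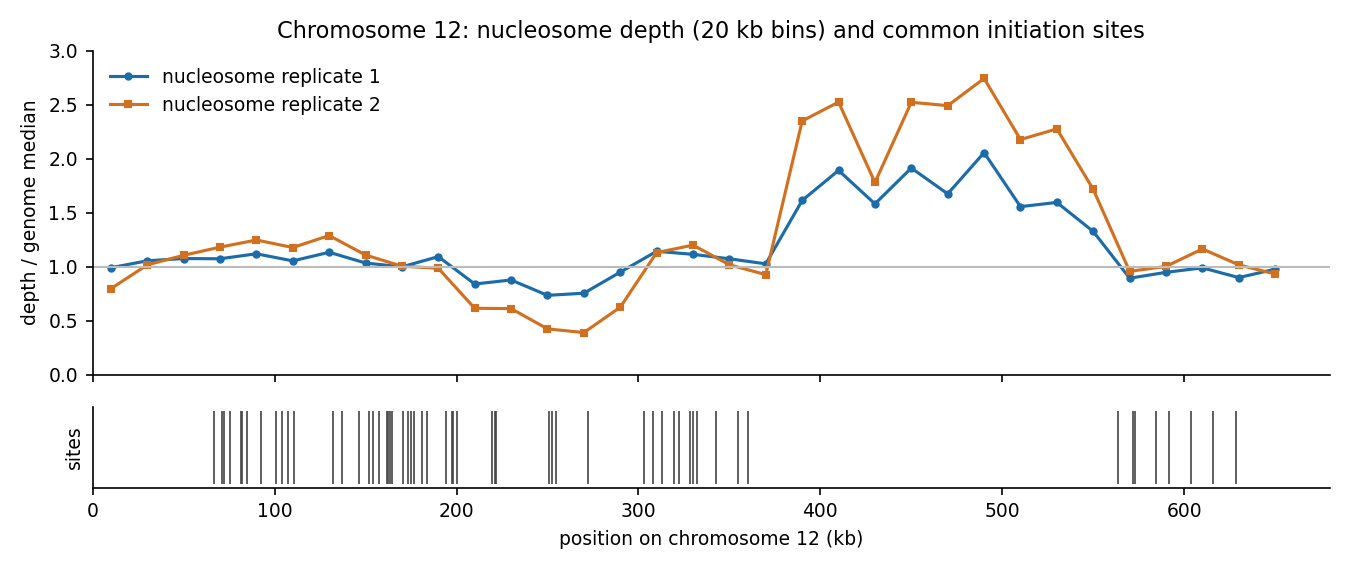
Nucleosome depth in 20 kb bins over the genome median along chromosome 12 (upper panel, replicates 1 and 2) and the midpoints of common initiation sites (lower panel, 1 line per site), by position in kb. The stretch from 360453 to 563522 holds no common site, and its depth is 1.56 in replicate 1 and 2.01 in replicate 2.

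The nucleosome libraries were used to ask how nucleosomes lay around initiation sites. Fragment midpoints, taken as nucleosome centres, were sparser at the sites than beside them. The log2 ratio of midpoints within 100 bp of the centre to those 500 to 1000 bp away was -0.19 in replicate 1 and -0.23 in replicate 2, with a mean of -0.21 ± 0.03 (SD, n = 2), a change of -13.5%. In replicate 2 midpoints at 500 to 1000 bp were still below the genome mean. With flanks at 1 to 2 kb the ratio was -0.21 in replicate 1 and -0.29 in replicate 2. With all F5 peaks as the site set and the flanks at 500 to 1000 bp the mean was -0.12, and with all F4 peaks it was -0.21. Random sites gave a mean of 0.00 and a lowest value of -0.03 over 1000 sets, so the two-sided permutation p was 0.001, the smallest they can give. These random sites were not matched on place between genes or on base composition. Midpoints fell to 0.860 of the genome mean at the lowest 50 bp bin in replicate 1 and to 0.817 in replicate 2. The dip was 400 bp wide at 50% of its depth in replicate 1 and 700 bp wide in replicate 2.

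**Figure D4:**
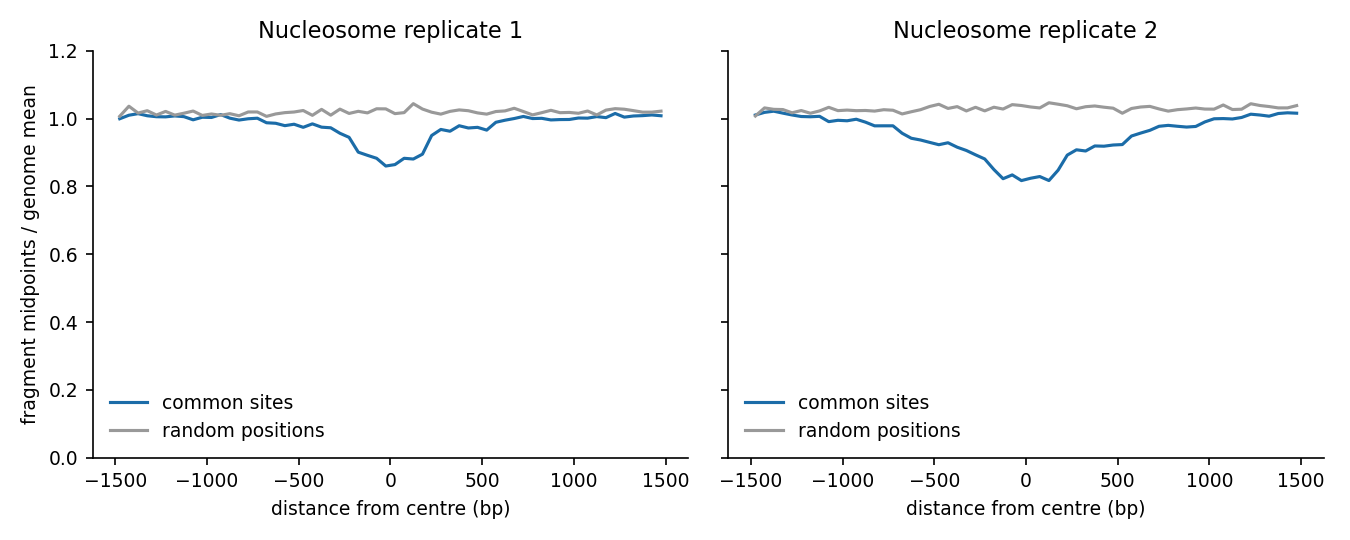
Nucleosome fragment midpoints over the genome mean, in 50 bp bins, by distance in bp from the centres of 4155 common sites (blue) and of random positions (grey), for each replicate. The lowest bin is at 0.860 in replicate 1 and 0.817 in replicate 2, and random positions stay between 1.01 and 1.05.

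The dip was spread over many sites. Midpoints were sparser at the centre than at the flank at 69.4% of sites in replicate 1 and 69.8% in replicate 2, against 50.2% and 48.7% of random positions. On chromosome 1 this held for 40 of the 57 sites in replicate 1, for 41 in replicate 2 and for 35 in both. The dip was deeper for longer fragments, with log2 ratios of -0.14 ± 0.05 from 120 bp to under 150 bp, -0.21 ± 0.06 from 150 bp to under 180 bp and -0.30 ± 0.07 for 180 bp and over (SD, n = 2). Each had a two-sided permutation p of 0.001, the smallest that 1000 sets can give, while the differences between the classes were not tested. For fragments under 120 bp the ratio was -0.059 ± 0.056 (SD, n = 2; two-sided permutation p = 0.13). The libraries differed in this call, with -0.020 in replicate 1 (permutation p = 0.61) and -0.098 in replicate 2 (permutation p = 0.009). These fragments made up 0.638% of replicate 1 and 1.85% of replicate 2.

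Nucleosome-depleted regions, stretches of 20 bp or more where smoothed midpoints fell under 0.4 of the local mean, lay near the sites more often than near random positions. In replicate 1, 18.1% of sites (95% Wilson interval 17.0 to 19.3%) lay within 200 bp of such a region, against 8.65% at random. In replicate 2 the shares were 35.8% (34.3 to 37.2%) and 21.0%. The mean was 27.0% ± 12.5 (SD, n = 2) against 14.8%, with a two-sided permutation p of 0.001, the smallest that 1000 sets can give. The libraries differed in the number of such regions, 6727 in replicate 1 and 16816 in replicate 2. This share changed with the threshold, to 11.5% against 7.50% at random under 0.2 of the local mean, and to 41.8% against 22.3% under 0.5.

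Peaks found in a single fraction were compared with shared peaks, since the fractions hold strands of different size. F5 peaks without an F4 partner had no dip, with a log2 ratio of 0.03 ± 0.01 against -0.14 ± 0.02 at shared F5 peaks (SD, n = 2). The difference of 0.17 had a two-sided permutation p of 0.0001, the smallest that 10000 permutations of the peaks can give. Their ratio was not distinguishable from that of random positions (two-sided permutation p = 0.14). With an overlap of at least 50% of the smaller peak needed for sharing, however, it was 0.06 and lay above random (two-sided permutation p = 0.005). F4 peaks without an F5 partner had a ratio of -0.23 ± 0.06, against -0.21 ± 0.03 at shared F4 peaks (SD, n = 2). That difference, -0.02, did not pass the two-sided test (permutation p = 0.26). In replicate 2 alone it was -0.04 (permutation p = 0.02), and in replicate 1 alone it was 0.01 (permutation p = 0.53). With the 50% overlap rule it was 0.02 in replicate 1 (permutation p = 0.026) and -0.02 in replicate 2 (permutation p = 0.14), so its direction was not settled.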

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

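The tests on the difference between fractions, on chromosome depth, on windows without fragments and on segments of high depth were chosen only after the results were seen, while those of unmappable sequence, short fragments, a few deep sites and digestion were set before their results.

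Being found in a single fraction went with different nucleosome levels in the 2 fractions. The log2 ratio of F5 peaks without a partner lay 0.17 above that of shared F5 peaks, and that of F4 peaks without a partner lay at -0.02 relative to shared F4 peaks. The difference between these effects was 0.18 (two-sided permutation p = 0.0005, the smallest that 2000 permutations can give), where the permutations assume no effect in either fraction. Its 95% bootstrap interval over 335 blocks of 100 kb, which needs no such assumption, was 0.14 to 0.22.

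Chromosome 23 had a depth of 1.57 times the median window in nucleosome replicate 1 and 1.03 times in replicate 2, a signal outside the measurement the libraries were made for. The ratio between the libraries was 1.52, against 0.856 to 1.11 for the other chromosomes, which argues against a trend over the whole library. It stayed at 1.33 or more in 38 of 38 bins of 20 kb (100%), which argues against a local amplification or a collapsed repeat. An extra copy of the chromosome in the culture of replicate 1 remains open as a hypothesis: the depth of 1.57 lies within 2 SD (0.0389 over the other 34 chromosomes) of 1.5, a value named after the depth had been seen. No biological explanation from the design was tested.

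Chromosome 31 had a depth of 1.92 times the median window in replicate 1 and 1.90 times in replicate 2.

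The fall of site density with chromosome length was weighed against mapping and depth, and no biological explanation was tested. Covered windows made up 96.7 to 100% of each chromosome, a range too narrow to give the 2.68-fold span in density. Per Mb of covered windows rho thus stayed at -0.77. This argues against windows without nucleosome fragments as the cause. Windows without reads in the nascent strand libraries could not be seen here. A first test of depth, over 34 chromosomes, took the depth of replicate 2 out of density alone and left r = -0.29 with length (two-sided permutation p = 0.091), where depth falls so closely as length rises that this r could not exceed 0.51 in size; with replicate 1 it left r = -0.62 (permutation p = 7e-05). A second test, added after that result was seen, took depth out of length as well and gave r = -0.57 with the depth of replicate 2 (two-sided permutation p = 0.0004) and r = -0.74 with that of replicate 1 (permutation p = 1e-05, the smallest that 100000 resamples can give). Density also rose with depth over these chromosomes, with rho = 0.54 in replicate 1 and rho = 0.70 in replicate 2. With replicate 2, the first test did not pass the threshold, the result that depth as the cause predicts. The first test with replicate 1 and the second with both replicates passed it, but the second was chosen after that result. The tests thus do not decide whether nucleosome library depth is the whole cause. The depth of the nascent strand libraries is unknown and stays open.

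The nucleosome dip at sites was weighed against 3 technical explanations. Random sites were not matched on place between genes or on base composition, so whether either gives the dip was not tested. Only 13 sites held a base of 0 coverage within 100 bp of the centre, against 26.8 on average at random. Without them the dip was -0.21, below every random set. This argues against sequence without any fragment as the cause, while sequence of reduced coverage was not tested. The median over sites was -0.22, so a few deep sites did not make the dip. Short protected particles in place of nucleosomes would raise the ratio of fragments under 120 bp. Its mean was -0.059, with -0.098 in replicate 2, below every random set there, and -0.020 in replicate 1, within its random sets. Nucleosomal DNA was cut out of gels, and these fragments made up 0.638% of replicate 1 and 1.85% of replicate 2. The ratio in such libraries cannot decide whether short particles lay at the sites. The deeper dip in replicate 2 was not removed by comparing fragments from 150 bp to under 180 bp alone. The difference between libraries there was 1.97 times (95% bootstrap interval over sites 1.77 to 2.26) that over all fragments. This argues against the mix of fragment lengths as its cause. Fragments of like length can come from libraries digested to different degrees, so the degree of MNase digestion stays open. Base composition was not tested.

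A segment of 160 kb on chromosome 12 (380001 to 540000) exceeded 1.4 times the median bin of its chromosome in both nucleosome libraries, at 1.62 and 2.13 times, and held no common site. There were 7 such segments, 280 kb in all, with 4 common sites against 29.6 at random (two-sided permutation p = 0.001, the smallest that 1000 placements can give). Of the 7 segments, 3 lie in stretches of over 50 kb chosen for holding no common site. These are 1 on chromosome 12 and 2 on chromosome 30 (stretch from 469525 to 544855). The other 4 segments held 4 common sites against 12.7 (two-sided permutation p = 0.018). Random sites were placed independently, whereas the sites were clustered, so both p-values may be too small.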

How the results depend on the processing

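Alternatives on fragment length, chromosomes 12, 23 and 31, paired or isolated sites, minimum spacing, depleted regions, density, the F5 to F4 ratio and the difference between fractions were added after the data were seen. Of the values recomputed, 56 kept their side of the threshold or, where no test was made, stayed near the main value. They also kept their direction, apart from the difference of F4 peaks without a partner from shared ones. That difference was -0.015 in the main setting. It was 0.00085 with the 50% overlap rule and 0.0073 without nucleosome replicate 2. With fragments under 120 bp the log2 ratio at sites was -0.059, no longer past the threshold, although replicate 2 alone passed it; the cause was not tested. The difference of F4 peaks without a partner from shared ones ranged from -0.038 to 0.0073 when a nucleosome library was left out, and passed the threshold without replicate 1. In 10 bp positions the correlation of the libraries was 0.66; the cause was not tested. The log2 ratio at sites ranged from -0.12 with all F5 peaks to -0.30 with fragments of 180 bp and over among the alternatives past the threshold. The cause of the smaller size with all F5 peaks was not tested. The median distance between sites was 3248 bp with all F5 peaks and 2609 bp with all F4 peaks, since these lists hold more peaks, and stayed below random. No paired analysis was possible because no label ties a fraction to a library. Not run were the upper part of each list by score or width, since peaks have no score and equal widths; circular shifts for spacing, which keep the distances; matching on base composition; and every alternative of the results that need genes. Depth limits the single sites more than the means over 4155 of them.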

Other observations

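The tests in this part were all chosen only after the results were seen.

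Chromosome 31, which Leishmania is known to carry in more copies than other chromosomes, had a site density 1.61-fold above the line of the other chromosomes, rank 1 of 36. As a hypothesis, DNA copy number may raise the number of peaks called there, but the rank restates the density that prompted it, and a single chromosome cannot separate copy number from its other properties. Short segments of high nucleosome depth held few peaks. Leaving out 3 that lie in stretches of over 50 kb with no common site, 4 remained. These held 6 F4 peaks, fewer than at random (two-sided permutation p = 0.002). They held 3 F5 peaks against 15.8 at random (two-sided permutation p = 0.001, the smallest that 1000 placements can give). Random peaks were placed independently, whereas the peaks were clustered, so these p-values may be too small. Why depth was high there was not tested, so these 4 segments do not decide on copy number. Chromosome 23, deep in replicate 1 of the nucleosome libraries alone, lay at 0.932-fold of its line.

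Whether F4 peaks without an F5 partner lie in blocks along the chromosomes was asked as a hypothesis. Of neighbouring F4 peaks, 72.2% had the same status, against 63.7% when the status was permuted within chromosomes, but close neighbours can meet the same F5 peak, which gives them the same status by construction. Among the 2483 F4 peaks with no other F4 peak within 2 kb the share was 61.7% against 59.5% (two-sided permutation p = 0.0076), a small excess that permutations also reached, with 62.9% at most. The longest run held 13 peaks of F4 alone, on chromosome 31 (572175 to 591696), and permutations reached 14. Blocks were thus neither excluded nor established.

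F5 peaks without an F4 partner were the more isolated ones: 233 of 635 (36.7%) lay within 2 kb of another F5 peak, against 58.7% of shared F5 peaks, a difference that was not tested.

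The distance from one nucleosome centre to the next, taken from the autocorrelation of midpoints, was 190 bp in replicate 1 and 172 bp in replicate 2, with correlations of 0.036 and 0.021, and no clear second maximum appeared in either library.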
